A study of Homo sapiens with 2 samples.

How the data were processed

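RNA was measured in whole semen from 2 normozoospermic samples. Per the labels' protocols, the ejaculate was washed in warm sperm washing medium and pelleted, RNA was extracted with warm TRIzol and treated with DNase, and ribosomal RNA was depleted. Libraries were primed with random primers from 500 ng of RNA, and 75-base reads were collected on a SOLiD 5500xl sequencer. Per the submitters' processing notes, TopHat2 2.0.6 and Bowtie were used with the hg19 build; how reads on several sites were treated and whether counting used strand are not given in the sources used here. The submitters state that the raw reads of sample 1 are incomplete, and whether the deposited values rest on all of its reads is not stated.

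The deposited table holds a coverage signal per gene and sample for 20316 rows, named by strand, chromosome and symbol. From the values, the deposited signal is the cube root of the average read coverage of a gene, scaled by the authors so that the median row is at 0.9996 in each sample. The cube root was examined on genes of 1 exon: the cubed value times the transcript length recurs at the same values across genes. A pair of these in the ratio of 35 to 50 bases was taken as the steps of reads of 35 and 50 aligned bases. The search kept only pairs in that ratio, so the ratio is not an independent check. The longer and shorter steps were held by 19 and 17 genes in sample 1 and by 11 and 5 in sample 2. Covered bases, read counts and floors rest on these steps. Why these lengths are below 75 bases is not given in the sources used here. The level of a gene is the deposited value cubed, so the median gene is close to 1. 1 covered base adds 1.00 to the level times length in sample 1 and 4.96 in sample 2, a ratio of 4.94. This gives 271 and 126 Mb of covered bases, of which the MTRNR2L genes hold 13.6% and 24.1%, and 234 and 95.7 Mb without them. Levels carry no correction for these genes.

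Gene lengths are the union of exons of GENCODE 29 transcripts that share a RefSeq accession with the row, found for 19182 of 20188 genes (95.0%). That annotation is of another build than the files, so no coordinates are given. Reads per gene were estimated from coverage, length and step size in units of 50 bases, and intervals of ratios are exact conditional 95% intervals for 2 Poisson counts. They cover counting error only, since reads without molecular identifiers are not independent molecules, and the lengths are approximate. A gene at 0 was given the level of 3 reads as its upper limit, per sample. At sample 2's depth, levels like those of sample 1 would leave 2636 of 19182 genes at 0, and 2766 were. Depth, here and in the thinning of sample 1, means reads at an equal level and length. It differed by the step ratio of 4.94, which is not the ratio of total covered bases.

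The 104 rows of chromosome Y and the XIST gene were left out, because the samples come from people. The row of the highest mean stood for a symbol with several rows, and 28 rows whose symbols are bare numbers cannot be named. The table holds 0 rows of the mitochondrial chromosome and 0 rows at 0 in both samples.

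Both samples form 1 group, so the comparison is between 2 libraries, not conditions, and no test or p-value of a difference between them was computed. Differences are log2((level + 1) of sample 2 / (level + 1) of sample 1), which understates the difference of low genes, among genes with a level of at least 1 in at least 1 sample, with a limit of 4-fold. The limits were written for a linear unit before its scale was known, and a level of 1 turned out to be close to the median gene of each sample. A list's median difference was set beside 10000 random lists of the same size, matched in 20 bins of mean level, and given a 95% interval from 10000 bootstrap draws of its members. Lists with under 3 compared genes have no median. For the spermatogonia, Sertoli cell, basal epithelium and fibroblast lists the interval equals the range of the compared members, so it cannot be read as a 95% interval. Random lists treat genes as unrelated, so a percentile describes these libraries only.

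The 24 lists were protamines and transition proteins, sperm tail and outer dense fibre, acrosome and egg binding, sperm energy metabolism and motility, spermatocyte and meiosis, spermatogonia, Sertoli cell, Leydig and testis interstitium, prostate, seminal vesicle, epididymis, neutrophil, macrophage and monocyte, lymphocyte, erythrocyte, glandular and urinary tract epithelium, basal and squamous epithelium, fibroblast and endothelium, mitochondrially encoded, cytosolic ribosomal proteins, stress and immediate early, nuclear and small noncoding RNA, interferon response, and widely expressed reference genes. They held 453 measured genes, 0 of them in more than 1 list. Genes named are the 15 of the highest mean log2(level + 1), the 10 of the largest difference in each direction among the upper quartile of mean level, and of each list the 3 of the highest mean and the 1 of the largest difference, 105 in all, of which some are not reported here. The lists, this rule, the limits and the other settings (pseudocounts, filters, scalings, fold limits, summed rows, ranks) were fixed before the data were examined. Thinning of sample 1, the GC correction, the restriction to genes over 300 bases with unshared values, the setting of zeros to 3 reads and the Sertoli cell list without ABP1, which does not belong in it, were added afterwards.

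The calculations were tested on simulated data. Reads drawn from equal levels at both depths put 10 genes past the limit in favour of sample 2 and 13 in favour of sample 1, of 10694. With 200 genes changed 8-fold, 100% of them passed, and likewise with 200 changed 16-fold. This recovery describes the genes changed in the simulation and does not extend to low genes. Adding 1 to each level understates their change, so a low gene changed 8-fold can miss the limit. Of 100 unchanged lists of 20 genes, 2 fell outside the middle 95% of random lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.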

Results

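Whole semen from 2 normozoospermic samples, meaning semen with normal sperm number, movement and form, was profiled by RNA sequencing. The labels place both in 1 group with 1 library each, and name no step that parts sperm from the other cells of the ejaculate. The series concerns RNA in clinical semen and sperm samples as diagnostic material. Its design allows 2 descriptions: which cell types the semen RNA represents, and how far the 2 samples differ. Levels are given on a linear scale on which the median gene of each sample is close to 1. Sample 1 was covered more deeply. Its genes had a median coverage of 0.999 reads per base against 0.204 in sample 2, and a median of 57.8 against 11.2 reads in units of 50 aligned bases. Of 20188 genes, 19786 (98.0%) were above 0 in sample 1 and 17212 (85.3%) in sample 2. A gene of the median length of 2856 bases listed at 0 could have had a level of up to 0.0528 in sample 1 and 0.260 in sample 2, the level of 3 reads. Intervals of ratios below are 95% intervals for counting error only, and with 1 library per sample no difference has a replicate check.

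Sperm transcripts led the protein-coding genes of both samples. PRM2 and PRM1 on chromosome 16 encode the protamines that pack sperm DNA, and reached levels of 2584 and 1824 in sample 1 and of 8905 and 1775 in sample 2. TNP1 on chromosome 2, a transition protein that acts before the protamines, stood at 1381 and 1229. CRISP2 on chromosome 6, a protein of the acrosome and tail, stood at 1141 and 6295. SMCP on chromosome 1, a protein of the capsule around sperm mitochondria, stood at 839 and 4716.

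The other 10 of the 15 genes of the highest mean were humanin-like genes, small RNAs and a pseudogene. MTRNR2L2, MTRNR2L8 and MTRNR2L1, nuclear copies of the gene for mitochondrial 16S ribosomal RNA, held levels of 11577, 10549 and 5590 in sample 1 and of 52103, 42616 and 17090 in sample 2. MTRNR2L10 stood at 655 and 4174, and MTRNR2L6 at 587 and 2806. The microRNA gene MIR4485 stood at 3245 and 12410. The small nucleolar RNAs SNORD46, SNORD89 and SNORD27 stood at 2062, 2031 and 1313 in sample 1 and at 750, 520 and 871 in sample 2. GUSBP9, a pseudogene of a family on chromosome 5, stood at 424 and 3955. Values of the MTRNR2L, MIR4485 and GUSBP rows are uncertain, since near-identical copies can share reads.

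Genes of mature sperm ranked high in both samples, and genes of the early germline and of testis soma ranked low. Ranks were taken among the 12030 genes with a level of at least 1 in at least 1 sample. Members outside that set were ranked against it, so a low percentile is not a share of all genes. A list is described by the median percentile of its members. The protamine and transition protein list (8 genes) lay at 85.2 in sample 1 and 85.4 in sample 2. The acrosome and egg binding list (18 genes) lay at 82.8 and 79.7, sperm energy metabolism and motility (26 genes) at 74.9 and 82.4, and sperm tail and outer dense fibre (24 genes) at 73.8 and 78.6. Spermatocyte and meiosis genes (23 measured) lay at 48.8 and 71.3. Spermatogonia genes (15 measured) lay at 0.931 and 4.26, Sertoli cell genes (15) at 1.51 and 3.69, and Leydig and testis interstitium genes (8) at 0.727 and 7.06. In this last list MYH11, a smooth muscle myosin, had levels of 0.528 and 3.49, CYP17A1, an enzyme of androgen synthesis, 0.180 and 0.504, and ACTA2 0.342 and 0.831.

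Among the remaining lists, the levels of gland, white blood cell and household genes depended on the sample. Prostate genes (22) lay at percentiles of 82.6 and 44.1, seminal vesicle genes (16) at 47.7 and 10.3, and epididymis genes (22) at 2.46 and 1.13. Neutrophil genes (27) lay at 86.5 and 14.2, and macrophage and monocyte genes (23) at 82.0 and 10.8. Lymphocyte genes (19) lay at 1.51 and 2.25, the second being the rank of PTPRC, whose value is below that of 1 read, and erythrocyte genes (8) at 0.303 and 2.89. A gene at 0 ranks at 0.133 in sample 1 and 1.13 in sample 2, so the lists below 5 in both samples lie close to the floor and their differences in rank are not read. Glandular and urinary tract epithelium (17 genes) lay at 7.84 and 4.38, basal and squamous epithelium (14) at 2.18 and 3.15, and fibroblast and endothelium (13) at 3.37 and 13.4. Cytosolic ribosomal proteins (53) lay at 97.6 and 92.5, nuclear and small noncoding RNAs (10) at 98.4 and 91.8, and widely expressed reference genes (20) at 94.2 and 75.8. Stress and immediate early genes (31) lay at 87.2 and 39.2, and interferon response genes (21) at 39.7 and 7.02. Of the mitochondrially encoded list, 0 genes were measured.

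**Figure D1:**
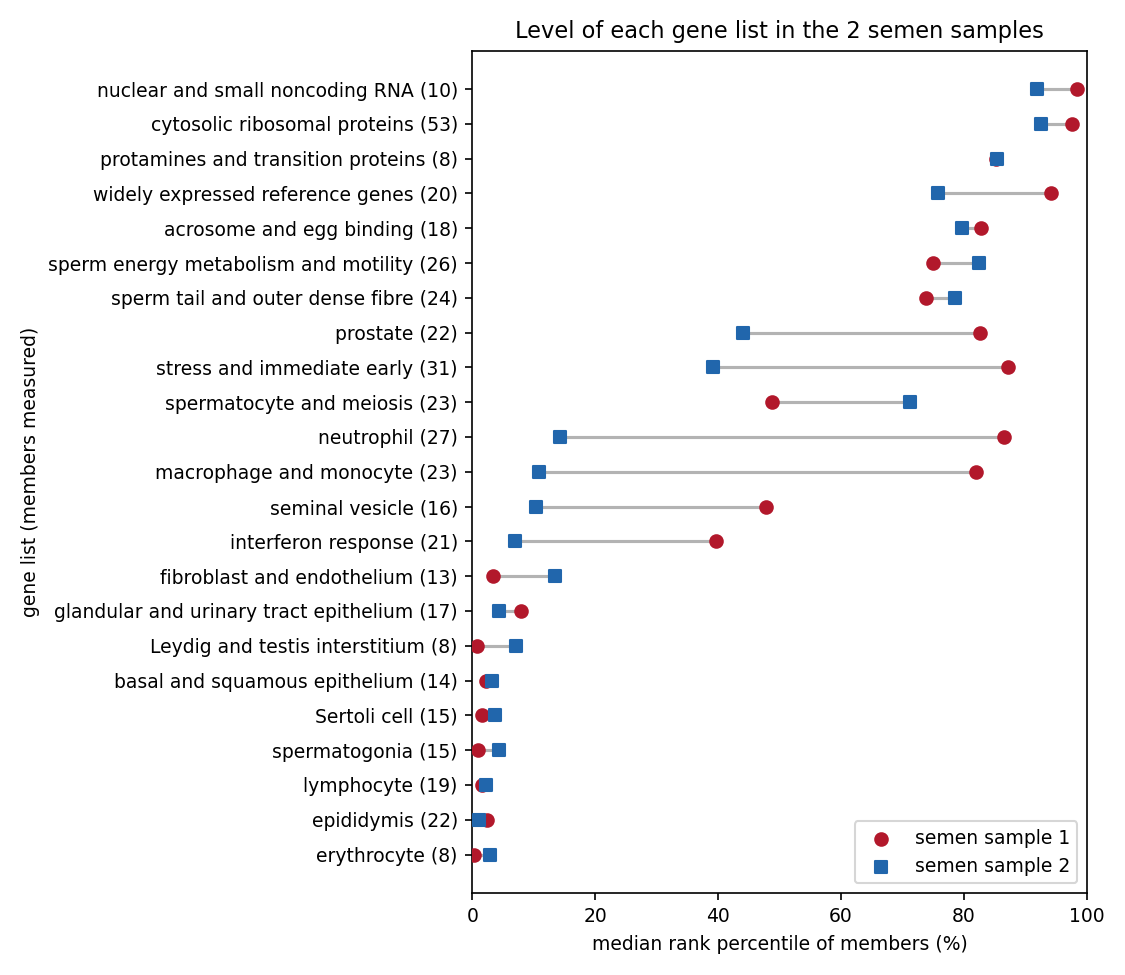
Median rank percentile of each gene list (x axis, in percent, among 12030 genes) in semen sample 1 (red circles) and semen sample 2 (blue squares), with the members measured in parentheses and a grey line joining the samples. The neutrophil list spans 86.5 to 14.2, while the protamine list stays at 85.2 and 85.4.

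Most genes at a level of 1 or more in either sample reached it in both. That level of at least 1 was reached by 8195 genes in both samples, by 1915 only in sample 1 and by 1920 only in sample 2. The last 2 counts are alike because each sample was scaled to a median close to 1. By contrast, 2976 genes were above 0 only in sample 1 and 402 only in sample 2. Across the 20188 genes, which are not independent replicates, Pearson's r of log2(level + 1) was 0.802 and Spearman's rho 0.781. Of the 12030 genes compared, 52.2% differed by less than 2-fold, and the median difference, sample 2 minus sample 1, was 0.39 on the log2(level + 1) scale.

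At least 4-fold differences on that scale were found for 873 genes higher in sample 2 and 496 higher in sample 1, so that 63.8% of the genes past the limit were higher in sample 2. This split turned with the fold limit, to 63 and 145 genes (30.3% higher in sample 2) at 8-fold, and with the scaling. Dividing sample 2 by the median ratio of the genes at 1 or more in both samples moved the median of all genes by −0.52 and gave 240 and 808 genes, with 22.9% higher in sample 2. Equal totals without the 50 highest genes moved it by −0.34 and gave 425 and 754 genes, with 36.0% higher in sample 2. Small nucleolar RNAs made up a part of the 496, with 50 of 88 SNORA and 77 of 205 SNORD genes. In the other direction, they gave 0 and 3 of the 873. Among genes over 300 bases with unshared values, 796 were higher in sample 2 and 320 in sample 1.

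**Figure D2:**
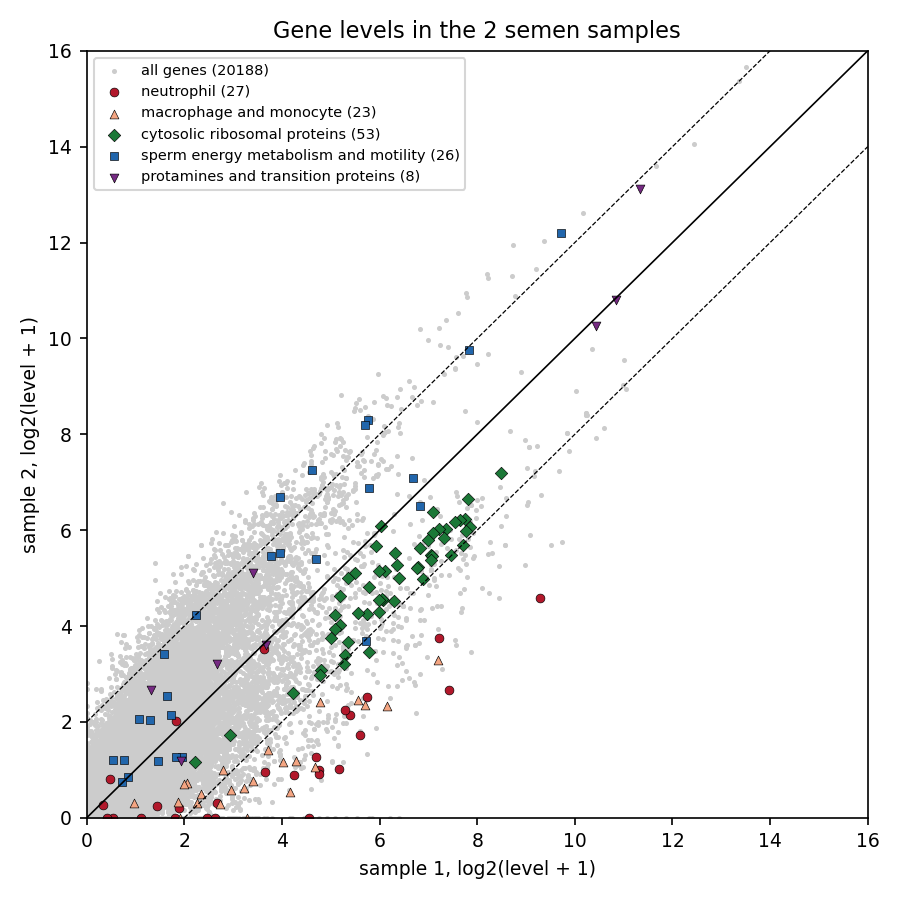
Log2(level + 1) of each of 20188 genes in sample 1 (x axis) and sample 2 (y axis), with 5 gene lists in colour, the line of equality and dashed lines at 4-fold differences. Most neutrophil and macrophage genes lie below the line, with list medians of −3.23 and −2.52, and 52 of 53 ribosomal protein genes lie below it too, with a median of −1.39.

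White blood cell genes had lower values in sample 2 for all but 1 of their compared members. Of 23 neutrophil genes compared, 17 were at least 4-fold lower in sample 2 and 0 higher. The median log2 difference of the list was −3.23 (95% bootstrap interval over members −3.76 to −2.36). The measured members left out, below 1 in both samples, were CXCR2 (0.448 and 0), CXCR1 (0.339 and 0), ALPL (0.392 and 0.764) and MMP25 (0.269 and 0.209). Which cells the RNA of this list came from was not tested. IL8, a neutrophil-attracting chemokine, had levels of 625 and 22.9, which is 27.3-fold lower in sample 2 (23.4 to 32.2). SRGN, a proteoglycan of leukocyte granules, had 170 and 5.34, or 31.8-fold lower (21.7 to 48.8), and SOD2, a mitochondrial superoxide dismutase, 147 and 12.4, or 11.9-fold lower (11.0 to 12.8). Of 22 macrophage and monocyte genes compared, 15 were at least 4-fold lower in sample 2 and 0 higher, with a median of −2.52 (−3.11 to −2.11), or −1.36 with a pseudocount of 5. HLA-DRA, which presents antigen to T cells, had 145 and 8.84, LYZ, the antibacterial enzyme lysozyme, 70.5 and 4.01, and SPP1, the secreted protein osteopontin, 51.2 and 4.14. Both medians lay at percentile 0 among 10000 random lists of the same size and mean level.

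Few lymphocyte and red cell genes reached a level of 1 in either sample. Only 2 of 19 lymphocyte genes could be compared, of which IL7R had levels of 4.45 and 0.156, a ratio of 28.5 on 3 reads in sample 2 (9.41 to 135), and CD4 2.85 and 1.15. GZMA had 0.392 and 0.941. Of 8 erythrocyte genes, HBB alone could be compared and was listed at 0 in sample 1 and at 1.19, or 3 reads, in sample 2, while HBA2 had 0.415 and 0.820 and AHSP 0.933 and 0.

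Stress, immediate early and ribosomal protein genes also had lower values in sample 2. Of 29 stress and immediate early genes compared, 18 were at least 4-fold lower in sample 2 and 0 higher, with a median of −2.38 (−2.62 to −1.44) at percentile 0, or −1.29 with a pseudocount of 5. HSP90AA1, a heat shock chaperone, had levels of 86.2 and 21.0 and HSPA1B, which has a near-identical copy, 93.0 and 11.1, whereas DNAJB1 had 41.9 and 28.1. IER3 had 27.0 and 0.740, a ratio of 36.5 on 4 reads in sample 2 (13.2 to 125). Of 53 ribosomal protein genes, 52 had lower values in sample 2 but only 3 by 4-fold or more, with a median of −1.39 (−1.52 to −1.20) at percentile 0. RPS6 had 357 and 145, RPS14 223 and 99.8, RPL7 215 and 74.7 and RPS16 54.2 and 10.1. These genes have many processed pseudogenes, which could share reads.

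The nuclear and small noncoding RNA, interferon and reference lists were lower in sample 2 as well. The 9 noncoding RNAs compared had a median of −2.31 (−2.82 to −1.34) at percentile 0.04, with 5 at least 4-fold lower and 0 higher. RMRP, the RNA of a nuclease that processes ribosomal RNA, had levels of 539 and 59.0, RPPH1, the RNA of ribonuclease P, 813 and 149, and the vault RNA VTRNA1-1 315 and 44.7. The 16 interferon response genes had a median of −1.07 (−1.49 to −0.72) at percentile 0.04, with 2 at least 4-fold lower and 0 higher, and the median was −1.86 with a pseudocount of 0.1 and −0.40 with 5. GBP1 had levels of 11.1 and 1.49, and IFITM1 6.35 and 3.11. IFITM3 was at 8.73 in sample 1 and listed at 0 in sample 2, at least 9.48-fold lower against the level of 3 reads. The 19 reference genes had a median of −0.78 (−1.79 to 0.12) at percentile 0.52, with 4 at least 4-fold lower and 0 higher, but went both ways; under the median ratio and equal total scalings the median was −1.38 and −1.16. B2M, at 300.1 and 24.7, was 12.2-fold lower and EEF1A1 2.78-fold lower (2.69 to 2.87) in sample 2, whereas GAPDH was 2.99-fold higher (2.86 to 3.12).

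Most secretory gland genes compared had lower values in sample 2. Of 20 prostate genes compared, 3 were at least 4-fold lower in sample 2 and 1 higher, with a median of −1.10 (−1.48 to −0.88) at percentile 0.02, or −0.67 with a pseudocount of 5. NEFH had levels of 49.3 and 15.2, whereas TGM4, a prostate transglutaminase, had 19.1 and 36.5. ORM1 had 9.04 and 0.296, a ratio of 30.6 on 1 read in sample 2 (5.15 to 1160). Of 10 seminal vesicle genes compared, 4 were at least 4-fold lower and 2 higher, with a median of −1.55 (−2.23 to 0.58) at percentile 0, which was −0.74 with a pseudocount of 5, −2.41 with 0.1 and −1.01 over all 16 measured genes. SEMG1 and SEMG2, which encode the gel proteins of the semen clot, were 5.52-fold (5.10 to 5.99) and 5.25-fold (4.65 to 5.95) lower, while CLU was 5.09-fold higher (4.60 to 5.63).

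Sperm gene lists had medians between 0.15 and 0.95. The 8 protamine and transition protein genes had a median of 0.24 (−0.17 to 1.70) at percentile 29.4, with 0 past the 4-fold limit, which turned to −0.31 and −0.12 under the median ratio and equal total scalings. PRM2 was 3.45-fold higher in sample 2 (3.39 to 3.50), while the ratio of PRM1 was 0.973 (0.936 to 1.01) and that of TNP1 0.890 (0.848 to 0.933). The 17 acrosome genes had a median of 0.15 (0.07 to 1.09) at percentile 9.26, with 1 higher and 0 lower, which turned to −0.30 and −0.18 under those scalings. CRISP2 was the one past the limit, at 5.52-fold (5.43 to 5.60), and ADAM32 had levels of 18.1 and 48.9 and ACRBP 16.8 and 21.7. The 21 sperm tail genes had a median of 0.73 (0.30 to 1.46) at percentile 56.0, with 2 higher and 0 lower, and medians of 0.12 and 0.34 under those scalings. ODF1, an outer dense fibre protein, had 256 and 705, AKAP4, of the fibrous sheath, 215 and 356, CABYR 107 and 390, and SPATA18 31.3 and 191. The 24 genes of sperm energy metabolism had a median of 0.95 (0.46 to 1.82) at percentile 80.8, with 5 higher and 1 lower, and medians of 0.52 and 0.66 under those scalings and 0.54 with a pseudocount of 5. PGK2, a sperm form of a glycolytic enzyme, had 227 and 865, TSSK6, a kinase of late spermatids, 53.2 and 313, TSSK3 14.6 and 102, and SMCP was 5.62-fold higher (5.49 to 5.75).

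Most spermatocyte and meiosis genes had higher values in sample 2. Of 21 spermatocyte and meiosis genes compared, 17 had higher values, 3 of them by at least 4-fold with 0 lower, and the median was 1.44 (0.85 to 1.53) at percentile 99.8, or 0.91 and 1.13 under the 2 scalings and 0.75 with a pseudocount of 5. PIWIL1, which binds small RNAs of the germline, had levels of 24.1 and 116, MEI1 1.48 and 10.6, DDX4, a germ cell helicase, 19.8 and 35.1, and MAEL 28.1 and 26.5. Only 4 of 15 spermatogonia genes could be compared, with a median of 1.86 (−0.35 to 2.57) at percentile 97.7 and 2 at least 4-fold higher, and the median was 0.11 when all 15 measured genes entered. TSPYL5 had 12.6 and 79.7, SOHLH2 6.79 and 33.0, and DAZL 3.28 and 11.9.

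The other lists rested on few compared genes. For the Sertoli cell, basal and fibroblast lists, as for spermatogonia, the interval given is only the range of the compared members. The 4 Sertoli cell genes had a median of 1.14 (−0.61 to 1.35) at percentile 99.7 with 0 past the 4-fold limit, which became −0.013 when all 15 measured genes entered. SHBG had levels of 0.426 and 2.63 and BEX2 1.17 and 0.423. ABP1, on chromosome 7, encodes an amine oxidase and not the androgen-binding protein of Sertoli cells, and had 0.402 and 2.46; without it the median of the other 3 genes was 0.98. The 6 epididymis genes had a median of −0.78 (−1.54 to 1.41) at percentile 9.22, or −0.02 with genes at 0 set to the level of 3 reads and −0.15 over all 22 measured genes. NPC2 had 12.7 and 2.54, GPX5 1.04 and 7.51, and CRISP1 1.89 and 3.89. The 6 glandular epithelium genes had a median of 0.14 (−1.32 to 1.16) at percentile 36.2, which turned to −0.19 and −0.08 under the 2 scalings and to −0.22 over all 17 measured genes, with KRT18 at 36.8 and 8.96, KRT8 at 14.8 and 8.66, and MUC1 4.77-fold higher (3.05 to 7.30). The 3 basal epithelium genes SFN, SPRR3 and KRT10 had a median of −0.83 (−0.93 to −0.58) at percentile 14.6, or −0.078 over all 14 measured genes. The 5 fibroblast and endothelium genes had a median of 1.14 (−3.32 to 2.14) at percentile 96.3, or 0.14 over all 13 measured genes, with VIM 13.0-fold lower (8.67 to 19.6), CDH5 6.61-fold higher (5.19 to 8.36) and SPARC at 1.19 and 0.829. Of the 20 lists with at least 3 compared genes, 9 lay below the middle 95% of their random lists and 3 above it. If genes were unrelated, chance would put 1 list outside. With a pseudocount of 5 the Sertoli, epididymis, basal and fibroblast medians were 0.36, −0.22, −0.28 and 0.37, and with 0.1 they were 2.36, −1.61, −1.23 and 2.31.

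**Figure D3:**
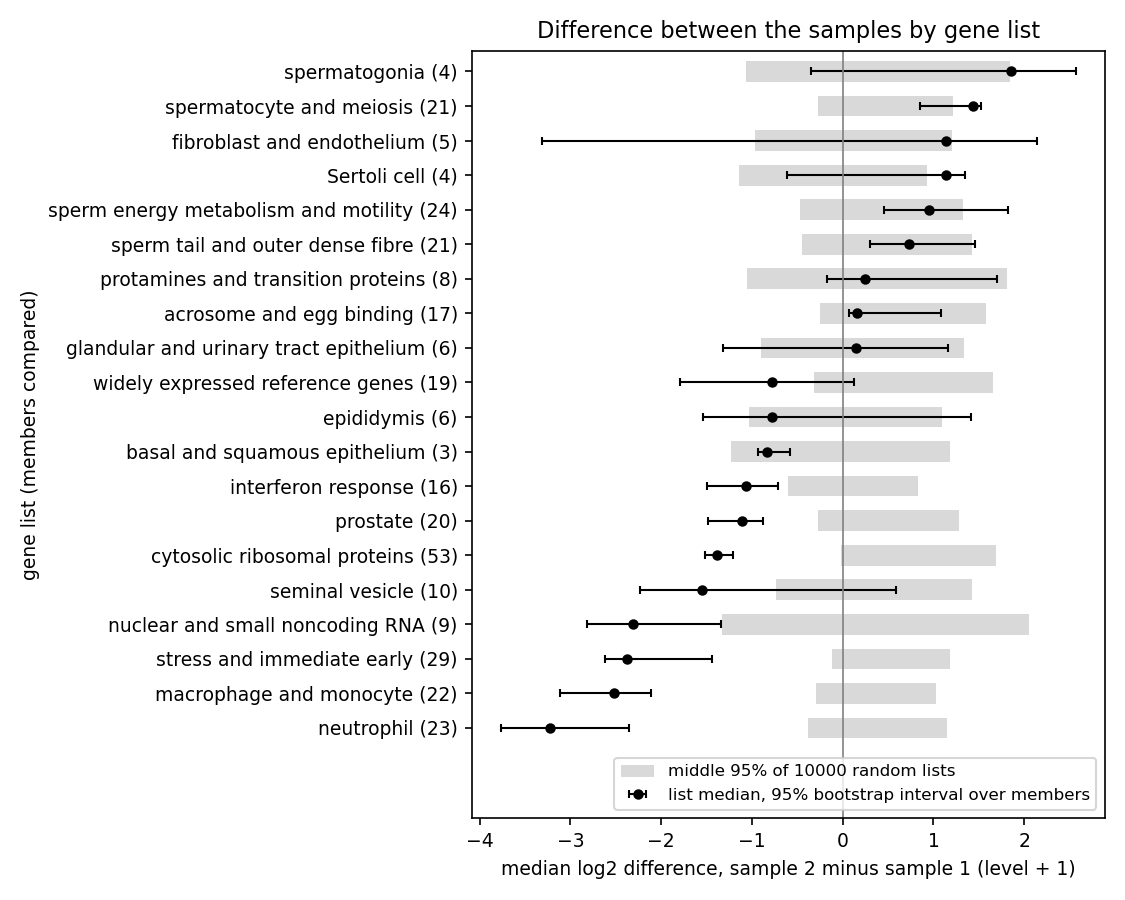
Median log2 difference of each gene list, sample 2 minus sample 1 on the level + 1 scale (x axis), with its 95% bootstrap interval over members (black) and the middle 95% of 10000 random lists of the same size and mean level (grey bars). Neutrophil (−3.23), macrophage and monocyte (−2.52) and stress genes (−2.38) lie furthest left, while the protamine, acrosome and glandular lists lie near 0 and change sign with the scaling. For the spermatogonia, Sertoli cell, basal and fibroblast lists the interval is only the range of the compared members.

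The single genes furthest apart among the 3008 most abundant compared genes are given for each direction. Whether their kinds differ between the directions was not tested. Higher in sample 2 were C9orf50 at levels of 1.66 and 39.1, or 23.6-fold (17.6 to 32.6), TREH, the enzyme that splits trehalose, 18.4-fold (14.6 to 23.5), and PAQR7, a membrane receptor for progesterone, 15.9-fold (14.2 to 17.9). MOSPD3, C3orf22, MAD2L2, ZNHIT2 and ACE, the angiotensin-converting enzyme, were 12.8-fold, 12.7-fold, 12.2-fold, 11.6-fold and 11.3-fold higher. LOC388242 and LOC613038 held identical values, 3.22 and 42.9, so their reads cannot be assigned to 1 of them. Higher in sample 1 were SRGN and IL8, given above, CTSL1, a lysosomal protease, at 52.7 and 1.51, or 34.8-fold (17.8 to 74.3), CXCL2, a neutrophil-attracting chemokine, 34.2-fold (14.8 to 107), and MT1G, a metal-binding metallothionein, 23.2-fold (14.6 to 41.6). MT1A had 37.2 and 1.25, a ratio of 29.7 on 2 reads in sample 2 (8.14 to 246). The small RNAs SCARNA5 and SNORA24 were 29.9-fold (11.5 to 109) and 20.3-fold (7.87 to 74.9) higher in sample 1. SNORD60 and SNORD91A had levels of 83.5 and 73.7 in sample 1 and were listed at 0 in sample 2, at least 9.32-fold and 9.41-fold lower against the level of 3 reads.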

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

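Of the tests below, the thinning of sample 1, the GC correction, the restriction to genes over 300 bases with unshared values, the setting of zeros to 3 reads and the Sertoli cell list without ABP1 were chosen after the data were seen. No paired analysis was possible because both samples belong to 1 group. Leaving out a sample leaves no difference to compute. Of 20 list medians, 17 kept their sign under each scaling, 18 without a filter, 18 with sample 1 thinned, and 20 under each pseudocount and with summed rows. With sample 1 thinned, the protamine median turned to −0.03 and the glandular epithelium median to −0.06. Of 55 named genes past the 4-fold limit, 41 stayed past it under the median ratio scaling, 46 under equal totals and 55 with a pseudocount of 0.1. Shallow coverage of sample 2 limits genes near its floor. Except where the setting itself changes which genes enter or how low values count, the cause was not tested.

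Agreement was 0.794 with a pseudocount of 0.1, 0.669 over genes at 1 or more in both samples, 0.792 on the cube root scale and 0.807 without small RNA and humanin-like genes. Genes detected in both samples numbered 16810 at any value above 0 and 2620 at a limit of 5. Genes higher in sample 2 and in sample 1 numbered 1936 and 1327 with a pseudocount of 0.1, 278 and 174 with 5, 240 and 808 under the median ratio scaling, 425 and 754 under equal totals without the 50 highest genes, 3710 and 2037 at a limit of 2-fold, and 63 and 145 at 8-fold. Over 300 bases with unshared values, they numbered 796 and 320.

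With a pseudocount of 0.1 list medians were 1.57 for spermatocyte, 2.36 for Sertoli cell, −2.41 for seminal vesicle, −1.61 for epididymis, −4.05 for neutrophil, −3.56 for macrophage, −1.23 for basal epithelium, 2.31 for fibroblast and endothelium, −3.25 for stress and −1.86 for interferon genes. With a pseudocount of 5 they were 0.75 for spermatocyte, −0.67 for prostate, −2.23 for neutrophil, −1.36 for macrophage, −0.28 for basal epithelium, −1.29 for stress and −0.40 for interferon genes. Under the median ratio scaling they were −0.31 for protamines, 0.12 for sperm tail, −0.30 for acrosome, −1.53 for prostate, −1.02 for basal epithelium, −1.97 for ribosomal proteins, −2.69 for stress and −2.90 for noncoding RNA. Under equal totals they were −0.18 for acrosome, −1.08 for basal epithelium, −1.77 for ribosomal proteins and −2.69 for stress. Without a filter the Sertoli cell median reversed to −0.013 and the basal epithelium median was −0.078.

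Ranked among all genes, mean list levels were 91.3 for protamines, 85.8 for sperm tail, 88.8 for acrosome, 87.3 for sperm energy, 76.2 for spermatocyte, 21.9 for spermatogonia, 22.5 for Sertoli cell, 24.4 for Leydig, 16.3 for epididymis, 17.3 for lymphocyte, 12.5 for erythrocyte, 33.5 for glandular epithelium, 22.8 for basal epithelium, 37.7 for fibroblast and endothelium and 49.6 for interferon genes.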

Other observations

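Gene families were compared after the lists had been read, and the tests of scaling, of the sperm share, of counting noise and of GC content were also chosen after the results were seen. Among 188 families of at least 8 compared genes with a shared symbol stem, 19 lay in the lowest 0.05% of random lists and 6 in the highest 0.05%, where chance gives 0.094 each. All 12 metallothionein genes, which bind zinc and copper, had lower values in sample 2, 11 of them by at least 4-fold, with a median log2 difference of −3.54. MT2A had levels of 145 and 14.3 and MT1X 96.2 and 6.51. The CC chemokine genes, signals that attract white blood cells, had 7 of 11 at least 4-fold lower and a median of −2.20, with CCL2 at 14.4 and 1.61 and CCL3 at 13.7 and 2.21. All 88 SNORA small nucleolar RNAs, guides of RNA modification, had lower values in sample 2, 50 by at least 4-fold, with a median of −2.12 that was −1.79 with genes at 0 set to 3 reads. The SNORD class had 186 of 205 lower and a median of −1.68, or −1.30 with genes at 0 set to 3 reads. The other 15 of the 19 had the stems ATP, CD, CXCL, EIF, HIST, HLA, MIR, MRPL, NDUFB, RAB, RPL, RPS, SCARNA, SNAR and SNHG. Of the 49 HIST genes, 13 were at 0 in sample 2, and their median of −1.16 was −0.59 with genes at 0 set to 3 reads.

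The 6 families in the highest 0.05% were of mixed kinds. The TTLL enzymes, several of which modify tubulin, had 10 of 11 higher values in sample 2, 6 by at least 4-fold, with a median of 2.01 that was 1.44 and 1.67 under the median ratio and equal total scalings. TTLL6 had levels of 8.50 and 73.0 and TTLL3 3.55 and 30.3. The ankyrin repeat genes (ANKRD) had 45 of 48 higher and a median of 1.37, or 0.83 and 1.05 under the scalings. The olfactory receptor genes (OR) had 21 of 22 higher and a median of 1.19, or 0.86 and 1.07. The CCDC, SLC and ZNF families had smaller medians of 0.98, 0.74 and 0.59, which were 0.45, 0.33 and 0.18 under the median ratio scaling.

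White blood cell genes lay far lower in sample 2, and 3 explanations were examined. A scaling factor may shift a list, but it shifts random lists of the same mean level alike. Of both lists, the median nearer to its random lists lay −2.95 (−3.54 to −2.54) from them. This gap restates percentile 0 among random lists, so it adds no separate evidence. With the reads of sample 1 thinned to the depth of sample 2 at an equal level, the neutrophil median was −3.05 (−3.46 to −2.33). Random thinning keeps the expected level of a gene, so this value bears on counting error only. A smaller share of sperm RNA in sample 1 alone would raise all other cell types alike, yet the neutrophil median lay −2.13 (−2.58 to −1.22) from the prostate median. This gap shows only that the 2 lists did not shift by 1 common factor. It cannot exclude that the sperm share took part, since 17 of 20 prostate genes were lower in sample 2 too and 3 higher. White blood cells in sample 1 stay open as a hypothesis. Of the 27 neutrophil genes, 20 were above 0 in sample 2 too, but so were 17212 (85.3%) of all 20188 genes. That count therefore decides nothing. PTPRC, a gene of nearly all white blood cells, cannot be read either way. Its levels of 0.000226 and 0.000604 are below what 1 read can give.

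Humanin-like genes were the highest in both samples. A candidate explanation, tested with a prediction made beforehand, is that reads of mitochondrial 16S ribosomal RNA were placed on nuclear copies. Across 8 MTRNR2L genes the mean level followed the percent of 50-base windows within 2 mismatches of MT-RNR2, with a Spearman's rho of 0.976 (exact two-sided permutation p = 0.000397). This percent was 59.1 for MTRNR2L2, 39.4 for MTRNR2L8 and 0.0673 for MTRNR2L7, whose levels were 0.252 and 0.166. Genes are not independent replicates, and expression of the copies themselves stays open.

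At the main scaling and the 4-fold limit, more genes were higher in sample 2 (873) than in sample 1 (496). This majority turned under the median ratio scaling (240 and 808 genes) and under equal totals (425 and 754). It also turned at an 8-fold limit (63 and 145). Counting noise alone put 10 of 10694 compared genes past the 4-fold limit in favour of sample 2 in simulated reads. The data gave 873 of 12030, which argues against counting error of independent reads as the cause of their number. Only such reads were simulated, for genes with a known length. Other noise, such as from library preparation, was not covered. With genes binned by GC content, those past the limit in favour of sample 2 rose from 43 of 1150 in the lowest bin to 197 of 1150 in the highest. Those in favour of sample 1 numbered 44 and 25 in these bins. Once all bins had the same median, 84.9% (694 of 817) stayed past the limit. A shift of the bin medians is thus not the whole cause. That step leaves the spread within bins as it was, so a part of GC content stays open. Scaling stays open: 27.5% (240 of 873) stayed past the limit under the median ratio scaling and 48.7% (425) under equal totals, but both scalings lower sample 2 against sample 1, so a loss was bound to follow and decides nothing. The design gives 1 group, so apart from the sperm share no biological explanation was tested for these 3 patterns.

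Some values were lower than 1 read can give, and were noticed after the values were seen. MSMB, a major protein of prostate fluid, had levels of 0.136 and 0.000239, which at its transcript length is 66.5 covered bases in sample 1 and 0.0238 in sample 2. PTPRC came to 1.67 and 0.903 covered bases. A value above 0 but under 1 covered base was held by 3 genes in sample 1 and 4 in sample 2. The pseudogenes SMA5 and GUSBP4, of the family of GUSBP9, had levels of 294 and 222 in sample 1 and of 2612 and 1869 in sample 2.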
